A study of Mus musculus with 21 samples.

How the data were processed

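RNA from mouse sciatic nerve was measured on Affymetrix arrays of 1 design, 21 arrays in 8 groups. Per the labels, each sample was a pool of nerves from 4 to 7 mice, amplified by 2 rounds of in vitro transcription, labelled with biotin and scanned with MAS 5.0. The authors normalized the scanner files in dChip with a smoothing spline and computed a model-based expression index for each probe set, per the labels. The probe sensitivities behind the index came from 27 arrays, or from 18 for the label of the first P60 WT array, so part of the arrays behind the model are not analysed here. The deposited values are this index, an intensity on a linear scale that can fall below 0. The dChip version and the choice between perfect-match and mismatch models are not given in the sources used here. Between 68 and 167 values per array were at or below 0.

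Groups were read from the labels: WT, KO, TG and TR at P4 with 3 arrays each, WT at P60 with 3, and KO, TG and TR at P60 with 2 each. The pools are the replicates, so p-values measure the spread between pools, which holds animals, preparation and array together, and not the spread between single mice. The deposited table held 12422 probe sets without control spots. Values were raised to a floor of 54.7, the 20th percentile of all values, and log2 was taken, with no further scaling because the authors had normalized the arrays. Probe sets above the floor on at least 2 arrays were tested, 10994 in all, and 1428 dim ones were left out. Fold changes are therefore understated for probe sets with arrays at the floor, and where a whole group lay there the change is a bound.

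Gene symbols came from the platform annotation: 10833 probe sets had 1 symbol, 396 had several and 1193 had none. Only probe sets with 1 symbol were named. Of these, 10817 matched a RefSeq gene of the GRCm38.p6 table through the Entrez identifier, and 0 symbols changed. No genome build is attached to the array values, so no positions are printed. Probe sets with the suffixes _f_at, _s_at, _r_at, _i_at or _g_at, and genes with close copies (Hspa1a and Hspa1b, Mup5, the hemoglobins), can take signal from related transcripts, and their values are uncertain in that respect.

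limma 3.58.1 in R 4.3.3 fitted 8 group means to all 21 arrays, with 13 residual degrees of freedom and eBayes with a trend, and Benjamini-Hochberg adjustment was applied within each comparison at 0.05. There were 16 comparisons: 6 of a mutant with WT at the same age, WT at P60 with WT at P4, 6 between mutants, and 3 tests of whether a mutant's effect differed between the ages. Errors printed with ± are standard errors from this fit for log2 changes, and SDs over arrays for index values. The comparisons, the tests, the gene lists and the rule for named genes were fixed before the data were examined. The rule took Pmp22 in each main comparison and the 6 highest and 6 lowest changes among called probe sets with 1 symbol and no overlap between the arrays of the groups. It added 3 members with the smallest adjusted p from each of the 5 lists with the smallest camera p. In comparisons between mutants and in tests of age it took 3 each way. Other probe sets of Ccnd1, Snhg6, Rfc1, Mb, Pkp2, Fdps, Mbp, Abca1, Ckm, Rit2, Stmn1, Myh4, Mki67, Vwf and Emcn had the opposite sign in a main comparison without passing the threshold. The same held for Meg3, Pkp2, Ctsc, Tmem50b, Serpinf1 and Ddx6 in the other comparisons, and no other probe set of a named gene was called in the opposite direction.

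Gene lists were tested with limma's camera against all 7703 genes, with the probe set of highest mean log2 value per gene, a preset correlation of 0.01 between genes, and adjustment over the 19 lists in each comparison. Counts of list members that rose or fell use that probe set only, so other probe sets of a member can have been called. The test was run again with an estimated correlation, which is reported beside each call. The lists were cholesterol biosynthesis, fatty acid and myelin lipid synthesis, myelin proteins, Schwann cell transcription regulators, immature, non-myelinating and injured Schwann cell, cell cycle, macrophage, antigen presentation and interferon response, T and B lymphocyte, mast cell, collagens and extracellular matrix, endoplasmic reticulum stress, cytosolic chaperones, proteasome and lysosome, adipocyte, skeletal muscle, endothelium, smooth muscle and pericyte, erythroid and blood, and neuron and axon. Of 472 genes on the lists, 383 were measured.

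Per the file headers, the arrays were scanned on 10 days. Scan day was tested as a fixed block, which could be fitted for 12 of the 16 comparisons and leaves 5 residual degrees of freedom. Both P60 TG arrays were the only arrays of their day, so that comparisons with that group used scan day as a random block through duplicateCorrelation, with a correlation of 0.396. Where a day held both groups of a main comparison, list medians within it were compared with the blocked ones. Where it held both groups of any comparison, probe sets were also called without its arrays in those groups and their sign was read on that day. Other alternatives were floors at the 10th and 40th percentiles (27.4 and 132.5), log2 of the value plus 50, quantile and median scaling, no filter and a stricter filter, eBayes without a trend, fits on the compared groups only, replicate number as a block, and each array left out in turn. Where an omission left 1 array in a group, that array was assumed to vary like those of the other groups.

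The steps were tested on simulated data with WT means and a pooled spread per probe set for all groups, 10994 probe sets of which 200 were changed. Changes were placed only in probe sets with means well above the floor. The shares below therefore do not cover dim probe sets or a group that spreads more than the others. For P4 KO against WT, 97% of 4-fold and 38.8% of 2-fold changes were recovered, with 6.19% of calls false. For P60 KO against WT the recovered shares were 92.4% and 56.7%, and for WT at P60 against P4 98.5% and 58.2%. For the test of whether the KO effect differed by age, 77.3% and 13.4% were recovered. The highest share of false calls was 12.2%, for P60 KO against TG. With scan day as a fixed block, 15.2% of 4-fold changes were recovered for P4 TR against WT. Over 7703 genes, a list changed in the simulation of P4 KO against WT was called in 20 of 20 runs, and unchanged lists were called in 3 of 360 tests. Because simulated genes were independent, these runs do not test calls of lists whose genes vary together. Figures were drawn in Python 3.11.15.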

Results

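Gene expression was measured in the sciatic nerve of mice with altered Pmp22, which encodes a tetraspan membrane protein of compact peripheral myelin. Pools of nerves were taken at postnatal day 4 (P4) and day 60 (P60) from wild type mice (WT), mice homozygous for a Pmp22 null allele (KO), mice carrying a Pmp22 transgene (TG) and Trembler mice (TR), which carry a point mutation in Pmp22. Median expression index per array ran from 177.4 to 209.6, and from 78.6% to 81.2% of probe sets lay above the floor of 54.7. The number of arrays, 3 per group at P4 and 2 per mutant at P60, limits the precision. Across probe sets, which are not independent replicates, Pearson's r between log2 values of arrays of 1 group ran from 0.932 to 0.987. Arrays of different groups could be as close, with r of 0.978 for P4_WT_3 and P4_KO_3. P60_KO_1 was closer to P60_WT_1 (0.958) than to P60_KO_2 (0.935). The first principal component held 36.8% of the variance and separated the ages, and the second held 16.6% and set P60_KO_2 apart at -60.2, against -18.7 to 27.1 for the other arrays. Genes said below to have risen or fallen passed an adjusted p of 0.05 in limma. In each comparison of 2 groups their arrays did not overlap, with genes shared between mutants and counts of list members aside. Chance alone gives no overlap for 10% of genes at 3 against 3 arrays, 20% at 2 against 3 and 33.3% at 2 against 2.

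Pmp22 itself had a mean index of 7205 ± 432 (SD over arrays) in P4 WT and 6895 ± 233 in P60 WT. In KO it was 5131 ± 292 at P4 and 5239 ± 624 at P60, with log2 changes from WT of -0.49 ± 0.11 (adjusted p = 0.0605) and -0.40 ± 0.12 (adjusted p = 0.0347). In TG it was 6695 ± 99.7 at P4 and 7970 ± 824 at P60, changes of -0.10 (adjusted p = 0.997) and 0.21 (adjusted p = 0.461). In TR it was 6679 ± 759 and 5553 ± 118, changes of -0.11 (adjusted p = 1) and -0.31 (adjusted p = 0.175). For this, the brighter of 2 probe sets, only the fall in P60 KO passed the threshold, and it did so without P60_KO_1 (-0.52, adjusted p = 0.0133) but not without any of the other 4 arrays, with -0.28 (adjusted p = 0.432) without P60_KO_2. The P60 KO fall also missed the threshold with median scaling, with a fit on the compared groups alone and with scan day as a block. The P4 KO fall passed with some other settings, given below. A dimmer probe set of the gene had means of 102, 38.9, 88.1 and 57.1 in P4 WT, KO, TG and TR, and of 122, 59.4, 108 and 47 at P60. It was called lower in P60 KO (-0.94, adjusted p = 0.0123) and P60 TR (-1.13, adjusted p = 0.00656), bounds with 1 KO and both TR arrays at the floor. Which part of the gene either probe set covers is unknown, so these values test neither the null allele nor the transgene.

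**Figure D1:**
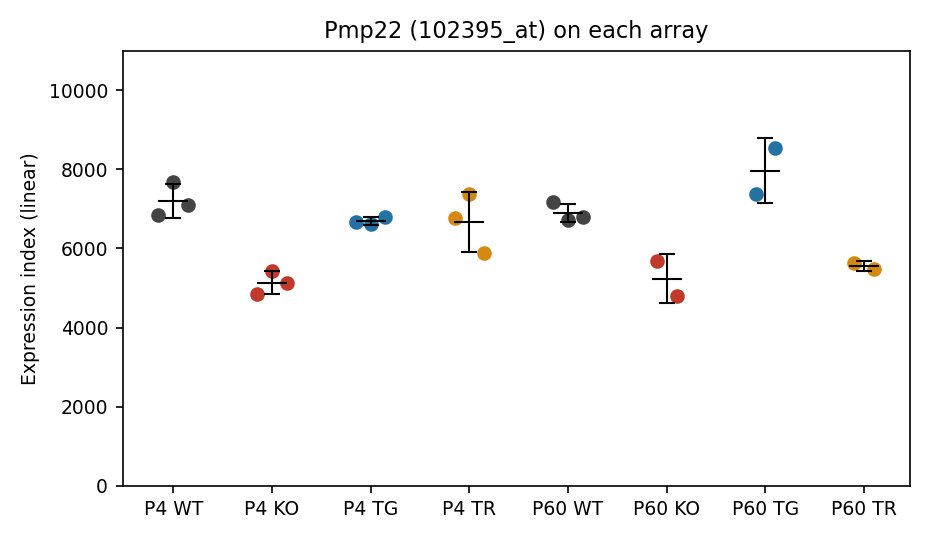
Expression index of the brighter Pmp22 probe set (linear axis) on each array, with points for arrays and bars for the group mean and SD. KO means were 5131 at P4 and 5239 at P60, against 7205 and 6895 in WT.

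**Figure D2:**
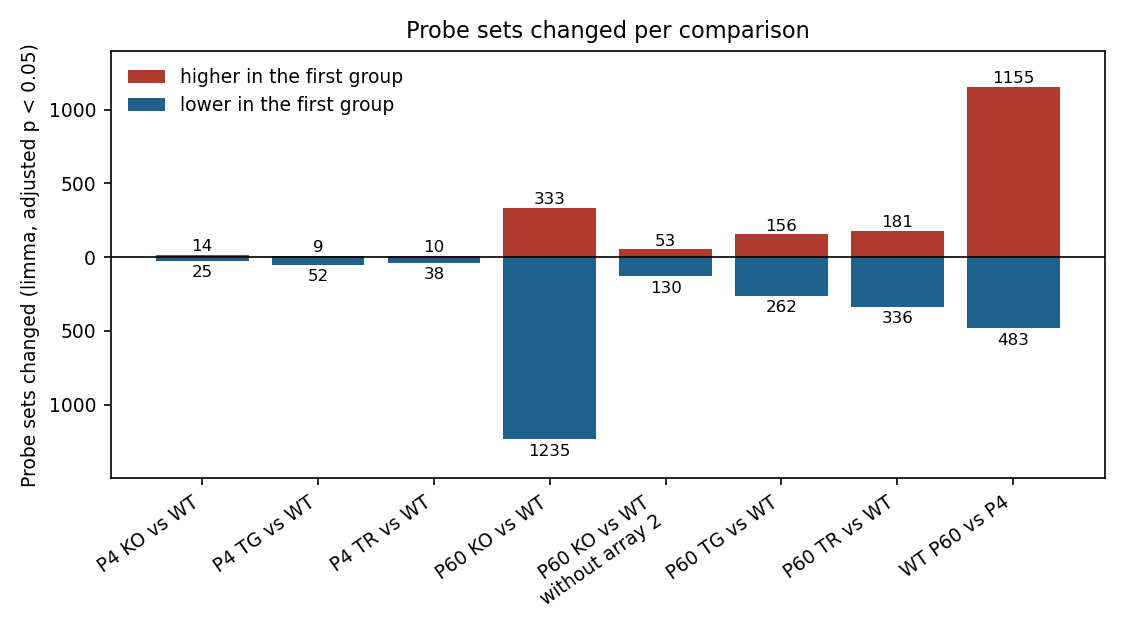
Number of probe sets past an adjusted p of 0.05 in limma in each comparison, higher drawn upward and lower drawn downward on a linear axis. For P60 KO the bars reach 333 and 1235 with both KO arrays and 53 and 130 without P60_KO_2.

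In P4 KO against WT (n = 3 and 3), the cholesterol synthesis gene Hsd17b7 fell by 2.31 ± 0.37 on the log2 scale, from 365 ± 124 to 71.2 ± 7.78. The fatty acid desaturase gene Scd1 fell by 0.80 ± 0.13, from 4746 ± 210 to 2721 ± 117. Among regulators of growth, Id2, an inhibitor of basic helix-loop-helix factors, rose by 0.85 ± 0.14 and the cyclin gene Ccnd1 rose by 0.96 ± 0.20. Of the largest falls, the snoRNA host gene Snhg6 changed by -3.18 ± 0.35 and Serpinc1, which encodes antithrombin, by -2.85 ± 0.31, both bounds, because 2 and 3 of the KO arrays lay at the floor. The expressed sequence AI506816 (-2.73), a probe set annotated to the microRNA gene Mir686, which does not measure the mature microRNA (-2.22), and the replication factor gene Rfc1 (-1.51) also fell. The adenosine kinase gene Adk rose by 1.23 ± 0.11 and the RNA-binding protein gene Hnrnpc by 1.61 ± 0.29, again bounds, with 2 WT arrays at the floor. The RING finger genes Rnf166 and Rnf227 rose by 1.44 and 1.29.

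Of 16 cholesterol biosynthesis genes, counted as in all lists by the brightest probe set of each, 1 (Hsd17b7) fell in P4 KO, while 9 fell when adjusted over the list alone. A dimmer probe set of Mvk was also called lower. Their median change was -0.65, with camera adjusted p = 3.65e-16 and adjusted p = 0.0311 with an estimated correlation. Idi1 missed the threshold at -0.84 ± 0.18 (adjusted p = 0.0505). Of 16 fatty acid and myelin lipid genes 1 fell by its brightest probe set (3 adjusted over the list alone; median -0.32) and Elovl6 by a dimmer one, and of 8 myelin protein genes none passed (median -0.32). In the cell cycle list, 1 of 44 genes rose, the replication gene Cdc45 at 0.76 ± 0.16, with a median of 0.54 and 19 risen when adjusted over the list alone. The skeletal muscle (median -0.56; 0 of 23 passed), erythroid (-0.19; 1 of 18 fell, the blood group gene Rhd at -1.09 ± 0.20) and neuron lists (-0.17; 0 of 16) were also called. With an estimated correlation the adjusted p = 0.224 for the fatty acid, myelin and cell cycle lists, 0.618 for muscle and 0.426 for the erythroid and neuron lists.

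limma called 39 probe sets in P4 KO, 14 higher and 25 lower, with 1178 at an unadjusted p under 0.05. The count was 25, 16 and 23 without P4_WT_1, P4_WT_2 or P4_WT_3 and 13 and 17 without P4_KO_1 or P4_KO_2. Without P4_KO_3 it was 46, of which 31 were higher and 15 lower, which turned the majority. Of 15 called genes named here, 7 to 12 passed without 1 array, and Adk, Snhg6, Serpinc1, AI506816, Hsd17b7 and Mir686 passed without any 1 array. Some lists missed the threshold without 1 array: erythroid (-0.04, adjusted p = 0.0618) and neuron (-0.16, 0.0537) without P4_WT_1, muscle (-0.05, 0.746) and neuron (-0.14, 0.199) without P4_WT_2, myelin without P4_WT_3 (-0.27, 0.0594) or P4_KO_1 (-0.23, 0.0784), and neuron without P4_KO_3 (-0.09, 0.136). No scan day held both groups, and as a fixed block it left 6 probe sets past the threshold, 1 of the 39 among them and none of the 15 genes, while the cholesterol (-0.45) and cell cycle (0.79) lists stayed past the threshold and the other 5 called lists did not.

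In P4 TG against WT (n = 3 and 3), the sterol pathway held 5 of the 6 largest falls. Idi1 fell by 2.03 ± 0.18, from 3728 ± 170 to 937.9 ± 272, and Cyp51 fell by 2.08 ± 0.28, from 1411 ± 526 to 318 ± 14.7. Fdps (-2.26), Nsdhl (-2.22) and Hsd17b7 (-1.97), further enzymes of cholesterol synthesis, fell as well. The growth factor gene Gdf5 changed by -2.63 ± 0.39, a bound with 2 TG arrays at the floor. Scd1 fell by 1.46 ± 0.13, the elongase gene Elovl6 fell by 1.29 ± 0.18 and Ugt8a, which makes the myelin lipid galactosylceramide, fell by 1.88 ± 0.30. Ndrg1, mutated in a hereditary neuropathy, fell by 0.69 ± 0.13. The endothelin receptor gene Ednrb rose by 1.62 ± 0.31, from 179 ± 74 to 525 ± 90.7. The desmosome gene Pkp2 (at least 1.24, all WT arrays at the floor), the whey acidic protein domain gene Wfdc18 (1.17), the thromboxane synthase gene Tbxas1 (1.11), the receptor phosphatase gene Ptprz1 (1.02) and the stress-induced gene Ddit4 (0.95) also rose.

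As a list, 9 of 16 cholesterol genes fell in P4 TG (13 adjusted over the list alone; median -1.18), with camera adjusted p = 7.15e-35 and adjusted p = 0.00106 with an estimated correlation. Of 16 fatty acid genes 3 fell and none rose (9 and 1 adjusted over the list alone; median -0.50; adjusted p = 0.0288 with an estimated correlation). Of 8 myelin protein genes 1 fell (5 adjusted over the list alone; median -0.56; adjusted p = 0.004 with an estimated correlation). The cell cycle list (median 0.38; 0 of 44 passed) and Schwann cell transcription regulators (median 0.18; 0 of 16 passed, 3 risen and 1 fallen when adjusted over the list alone) were called with the preset correlation. For these lists the adjusted p = 0.25 and 0.276 with an estimated correlation. Egr1 (0.81 ± 0.19, adjusted p = 0.0769), an immediate early transcription factor gene, and Id2 (0.54, adjusted p = 0.136) did not pass.

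limma called 61 probe sets in P4 TG, 9 higher and 52 lower, with 739 at an unadjusted p under 0.05. The count was 34 and 37 without P4_WT_1 or P4_WT_3, 25 without P4_TG_1 or P4_TG_2 and 74 without P4_TG_3. Of 17 called probe sets of the genes named here, 8 to 16 passed without 1 array. Those of Gdf5, Cyp51, Idi1, Scd1, Elovl6 and Ugt8a and 1 of 2 of Nsdhl passed without any 1 array. The regulators' call was lost without P4_WT_2 (0.06, adjusted p = 0.245) or P4_TG_1 (0.12, adjusted p = 0.123). The groups shared no scan day, and with scan day as a fixed block 5 probe sets passed, none of the 61 among them. Of these 5, 3 were higher and 2 lower, which turned the majority. With that block the cholesterol (-1.14), fatty acid (-0.54), myelin (-0.45) and cell cycle (0.66) lists stayed past the threshold and the regulators did not (0.32, adjusted p = 0.679).

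In P4 TR against WT (n = 3 and 3), the inducible Hsp70 genes rose most: Hspa1a by 4.42 ± 0.24, from 79 ± 11.4 to 1721 ± 417, and Hspa1b by 3.52 ± 0.23, from 383 ± 59.9 to 4370 ± 27.4. These are near-identical copies, so the split between them is uncertain. The cytosolic chaperone gene Hsp90aa1 rose by 1.14 ± 0.14, from 2041 ± 172 to 4476 ± 142. Cxcl10, an interferon-induced chemokine gene, rose by 1.63 ± 0.16, and the cell cycle inhibitor gene Rprm (1.58) and the asparagine synthetase gene Asns (1.14) rose as well, all 3 bounds, with 2 WT arrays at the floor. Clvs1, which encodes a lipid-binding protein of endosomes, rose by 1.54. S100b, a glial calcium-binding protein gene, fell by 2.00 ± 0.27, from 767 ± 115 to 194 ± 42.2. Hmgcs1, an early enzyme of cholesterol synthesis, fell by 1.68 ± 0.25, from 3586 ± 113 to 1121 ± 70.3, and Fdps (-1.79), Nsdhl (-1.74) and Idi1 (-1.27) fell too. Gdf5 (-2.24), Elovl6 (-1.62), Scd1 (-1.38) and the fatty acid synthase gene Fasn (-1.09) were also lower.

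Of 16 cholesterol genes 10 fell in P4 TR (13 adjusted over the list alone; median -1.07; camera adjusted p = 3.4e-29, and adjusted p = 0.00249 with an estimated correlation). Of 16 fatty acid genes 3 fell (6 adjusted over the list alone; median -0.38), and no myelin protein gene passed (4 of 8 fell when adjusted over the list alone; median -0.35), both at adjusted p = 0.0356 with an estimated correlation. In the chaperone, proteasome and lysosome list 4 of 30 genes rose (9 risen and 1 fallen when adjusted over the list alone; median 0.25; adjusted p = 0.139 with an estimated correlation). The cell cycle (0.29; 0 of 44 passed) and neuron (0.16; 0 of 16) lists were called at adjusted p = 0.33 and 0.256 with an estimated correlation.

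limma called 48 probe sets in P4 TR, 10 higher and 38 lower, with 739 at an unadjusted p under 0.05. The count was 31, 26, 19 and 16 without P4_WT_1, P4_WT_3, P4_TR_1 or P4_TR_2, and 80 without P4_TR_3. Of 18 called probe sets of the genes named here, 13 to 16 passed without 1 array. Without any 1 array 12 passed: those of Hspa1a, Hspa1b, Cxcl10, Rprm, Asns, S100b, Hmgcs1, Idi1, Scd1 and Hsp90aa1 and 1 of 2 each of Nsdhl and Elovl6. Fdps missed the threshold without each of the 6 arrays (adjusted p from 0.0938 to 0.169) and with replicate number as a block (-1.79, adjusted p = 0.0718). The neuron list missed the threshold without P4_TR_1 (0.13, adjusted p = 0.193). Without the 2 arrays of scan day 3, 1 of each group, 10 probe sets were called, and 10 of 10 had the same sign between those 2 arrays. A fixed block of scan day left 16 probe sets, 6 of the 48 and Hspa1a, Hspa1b, Rprm, Fdps and Hsp90aa1 among them. Of these 16, 9 were higher and 7 lower, which turned the majority. The block gave the lists their medians within that day: cholesterol, at -1.18, kept its call, while myelin (-0.20, adjusted p = 0.107) and neuron (0.10, adjusted p = 0.223) lost theirs.

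**Figure D3:**
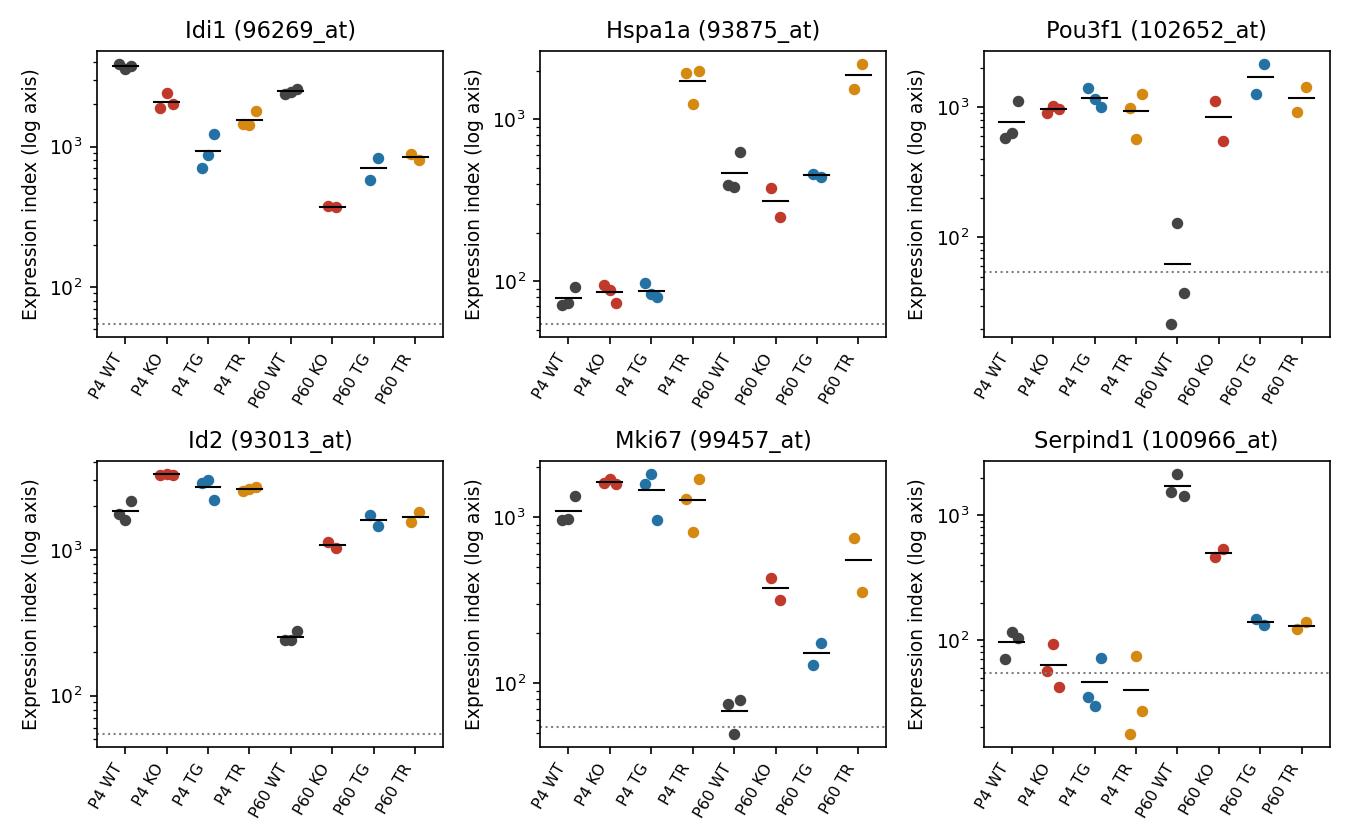
Expression index (log axis) of 6 genes on each array, with a bar at the group mean and a dotted line at the floor of 54.7; values under 1 are drawn at 1. Hspa1a was at 1721 in P4 TR against 79 in P4 WT, and Pou3f1 was at 62.9 in P60 WT, below its mean in each P60 mutant.

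In P60 KO against WT (n = 2 and 3), Pou3f1, a transcription factor gene of promyelinating Schwann cells, rose by 3.43 ± 0.42, from 62.9 ± 58.2 to 834.6 ± 405, a bound with 2 WT arrays at the floor. Id2 rose by 2.11 ± 0.16, from 252 ± 21.9 to 1086 ± 76.8, and Sox2, a transcription factor gene of immature Schwann cells, rose by 1.48 ± 0.27. Abca1, a cholesterol exporter gene, rose by 2.62 ± 0.30, and Socs3, an inhibitor of cytokine signalling, rose by 2.38 ± 0.24. The matrix gene Tnc (2.90), the disintegrin gene Adam2 (2.62) and the proliferation marker gene Mki67 (2.42) rose too. Among sterol genes Idi1 fell by 2.73 ± 0.20, from 2472 ± 97 to 373 ± 2.42, and Sqle fell by 2.05 ± 0.22. Fdps (-4.02) and Sc5d (-2.72) also fell. Genes of fast skeletal muscle had the largest falls, Myh4 at -5.00 ± 0.97, Tnnt3 at -4.66, Mylpf at -4.39, Ckm at -4.18 and Atp2a1 at -4.06, each with 1 KO array at the floor. The muscle genes Pygm (-1.41, both KO arrays at the floor), Tnni2 (-3.72) and Pvalb (-1.85) fell as well. The major histocompatibility gene H2-K1 fell by 1.46 ± 0.23, the interferon-induced gene Ifit3 fell by 2.31 ± 0.29 and the peptide transporter gene Tap2 fell by 0.65 ± 0.09, a bound with both KO arrays at the floor. In lipid synthesis Fads1 (-1.88), Elovl6 (-1.04) and Sptlc2 (adjusted p = 0.00473) fell.

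Of 16 cholesterol genes 14 fell in P60 KO, also when adjusted over the list alone (median -1.64; camera adjusted p = 2.87e-13; adjusted p = 0.0641 with an estimated correlation). Of 22 antigen presentation and interferon genes 12 fell (13 adjusted over the list alone; median -0.76; adjusted p = 0.161 with an estimated correlation). Of 23 skeletal muscle genes 13 fell (median -1.85; adjusted p = 0.393 with an estimated correlation), and of 16 fatty acid genes 1 rose and 4 fell (1 and 7 adjusted over the list alone; median -0.57; adjusted p = 0.393 with an estimated correlation). Of 16 Schwann cell regulators 5 rose (6 adjusted over the list alone; median 0.26; adjusted p = 0.123 with an estimated correlation). Of 35 matrix genes 2 rose and 11 fell (4 and 16 adjusted over the list alone; median -0.37), and of 30 chaperone genes 1 rose and 9 fell (median -0.47), both at adjusted p = 0.464 with an estimated correlation. In the cell cycle list 4 rose and 2 fell (median 0.11; adjusted p = 0.512 with an estimated correlation). Lists that missed the threshold held called members: 4 mast cell, 3 endothelial, 4 adipocyte and 4 smooth muscle genes fell, and 2 myelin protein genes fell around a median of -0.17 (adjusted p = 0.302).

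limma called 1568 probe sets in P60 KO, 333 higher and 1235 lower, with 3211 at an unadjusted p under 0.05. Quantile scaling gave 626 higher and 948 lower, and median scaling 644 and 973. The count was 183 (53 higher, 130 lower) without P60_KO_2, 2325 without P60_KO_1 and 845 without P60_WT_3. Of 26 called genes named here 19 passed without any 1 array. Without P60_KO_2, Tnc (2.62), Adam2 (2.11), Sox2 (1.25), Elovl6 (-0.75) and Sptlc2 (-0.73) missed the threshold, with adjusted p from 0.0512 to 0.175. Mylpf did so without P60_KO_1 (-3.54, adjusted p = 0.0501), and Atp2a1 without P60_KO_1, P60_WT_2 or P60_WT_3, with -2.35 (adjusted p = 0.236) without P60_KO_1. Among lists, fatty acid (-0.33, adjusted p = 0.0978), matrix (-0.30, 0.136) and chaperones (-0.20, 0.28) were lost without P60_KO_2, matrix without P60_WT_3 (-0.31, 0.122) and cell cycle without P60_KO_1 (median 0, adjusted p = 0.0893). No scan day held both groups, and as a fixed block it left 5 probe sets, 1 of the 1568 among them and none of the genes named here, while matrix (-0.13, adjusted p = 0.166) and chaperones (-0.25, adjusted p = 0.234) were the only called lists lost, and cholesterol stood at -1.98, antigen at -1.22 and muscle at -1.93.

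In P60 TG against WT (n = 2 and 3), Pou3f1 rose by 4.5 ± 0.42 (a bound, 2 WT arrays at the floor), Id2 by 2.67 ± 0.16, to 1605 ± 203, and Sox2 by 1.53 ± 0.27. Fbp1, a gluconeogenic enzyme gene, rose by at least 4.66 ± 0.22, to 1418 ± 458, and Tyrp1, a melanin synthesis gene, rose by at least 3.81 ± 0.41, to 769 ± 6.1, each with all 3 WT arrays at the floor. Csrp2, a LIM domain protein gene, rose by 3.31 ± 0.34, from 279.8 ± 92 to 2729 ± 683. The small GTPase gene Rit2 (3) and the ankyrin repeat gene Sowaha (2.90) rose too. Serpind1, heparin cofactor, fell by 3.59 ± 0.27, from 1706 ± 396 to 139.7 ± 10.1, and the collagen crosslinking enzyme gene Lox fell by 3.23 ± 0.41, from 2340 ± 116 to 292 ± 216. The growth factor genes Fgf4 (-2.62) and Fgf1 (-2.44), the cation transporter gene Slc22a2 (-2.54, both TG arrays at the floor) and the protease inhibitor gene A2m (-2.40) fell. In the sterol pathway Idi1 fell by 1.83 ± 0.20, Sqle fell by 1.58 ± 0.22 and Sc5d fell by 2.26. The matrix genes Ogn (-1.40) and Col4a1 (-0.50), the immune genes Ifit3 (-1.24) and H2-Eb1 (-1.11) and the muscle gene Pygm (-1.41, both TG arrays at the floor) fell. Tap2 rose by 0.35.

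Of 16 cholesterol genes 8 fell in P60 TG (13 adjusted over the list alone; median -1.15; camera adjusted p = 7.8e-14), and of 16 Schwann cell regulators 5 rose (7 adjusted over the list alone; median 0.39), both at adjusted p = 0.0426 with an estimated correlation. Of 22 genes of immature and injured Schwann cells 3 rose (median 0.12; adjusted p = 0.288 with an estimated correlation). Of 22 antigen genes 1 rose and 2 fell (1 and 5 adjusted over the list alone; median -0.58). Of 35 matrix genes 5 fell (1 risen and 8 fallen when adjusted over the list alone; median -0.17), and of 23 muscle genes 1 fell (5 adjusted over the list alone; median -1.07). The adjusted p = 0.454 with an estimated correlation for the antigen, matrix and muscle lists. Of 16 endothelial genes 1 rose and 2 fell (1 and 4 adjusted over the list alone; median -0.45). No macrophage gene of 24 passed (4 fell when adjusted over the list alone; median -0.29), and for both lists adjusted p = 0.487 with an estimated correlation. No cell cycle gene passed (median 0.10; adjusted p = 0.68 with an estimated correlation).

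limma called 418 probe sets in P60 TG, 156 higher and 262 lower, with 1764 at an unadjusted p under 0.05, and 121 without P60_TG_2. Of 24 called probe sets of the genes named here 18 passed without any 1 array. Without P60_TG_2, H2-Eb1 was at -0.47 (adjusted p = 0.713), and Sox2 (1.46), Ifit3 (-1.34), Ogn (-1.23) and Col4a1 (-0.55) missed the threshold at adjusted p from 0.0709 to 0.218. Ifit3, Tap2, H2-Eb1 or Col4a1 also missed it without P60_WT_1 (up to 0.0673), P60_WT_2 (0.0741), P60_WT_3 (up to 0.121) or P60_TG_1 (up to 0.218). Of 9 called lists, immature Schwann cell, cell cycle, macrophage, matrix and endothelium were lost without P60_TG_2, with medians of 0.04, 0.11, 0.003, -0.08 and -0.38 (adjusted p from 0.0567 to 0.514). The macrophage mean differed from WT by 0.04 on P60_TG_1 and by -0.88 on P60_TG_2, so the printed median rests on 1 array. The same lists and antigen were lost without P60_WT_3 (0.0793 to 0.188), cell cycle without P60_WT_2 (0.0773) or P60_TG_1 (0.119), and endothelium without P60_TG_1 (0.0624). The TG arrays were the only arrays of their scan day, so genotype and scan day cannot be told apart. With scan day as a random block 174 probe sets passed, all among the 418, with 20 of the 24 of named genes (not Ifit3, Tap2, H2-Eb1 or Col4a1) and all 9 lists.

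In P60 TR against WT (n = 2 and 3), Pou3f1 rose by 3.97 ± 0.42 (a bound, 2 WT arrays at the floor), Id2 by 2.74 ± 0.16, to 1689 ± 186, and Sox2 by 1.56 ± 0.27. Csrp2 rose by 3.33 ± 0.34 and Clvs1 rose by 3.01 ± 0.34, from 373 ± 113 to 3001 ± 1080. Tyrp1 rose by at least 3.25, and Adam2 (2.93), Mki67 (2.91 ± 0.34) and the mitotic kinase gene Cdk1 (2.20) rose. Serpind1 fell by 3.68 ± 0.27, to 131 ± 12.4, and the synuclein gene Sncg fell by 3.66 ± 0.61. Hmgcs1 fell by 2.33 ± 0.28, from 2336 ± 182 to 465 ± 20.7, Sqle fell by 1.87 ± 0.22 and Sc5d changed by -3.10, a bound with 1 TR array at the floor. Elovl6 (-1.64), Fads1 (-2.15) and the microtubule regulator gene Stmn1 (-2.04) fell. Muscle genes fell by large amounts, Tnnt3 at -4.39 ± 0.91, Atp2a1 at -4.28, Ckm at -4.06, Myh4 at -3.98, Pvalb at -1.84 and Pygm at -1.41, with both TR arrays at the floor for Pygm and 1 for Tnnt3, Atp2a1, Ckm and Sncg.

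Of 16 cholesterol genes 11 fell in P60 TR (12 adjusted over the list alone; median -1.25; camera adjusted p = 1.59e-17; adjusted p = 0.0228 with an estimated correlation). Of 23 muscle genes 8 fell (13 adjusted over the list alone; median -1.84; adjusted p = 0.143 with an estimated correlation). Of 16 fatty acid genes 2 fell (6 adjusted over the list alone; median -0.50; adjusted p = 0.137 with an estimated correlation), and of 8 myelin protein genes 1 fell (4 adjusted over the list alone; median -0.37; adjusted p = 0.108 with an estimated correlation). In the cell cycle list 7 of 44 rose and 1 fell (9 and 1 adjusted over the list alone; median 0.38; adjusted p = 0.279 with an estimated correlation). Of 16 Schwann cell regulators 5 rose and 1 fell (6 and 1 adjusted over the list alone; median 0.34). Of 9 mast cell genes 4 fell (1 risen and 4 fallen when adjusted over the list alone; median -0.29), and both lists had adjusted p = 0.0939 with an estimated correlation. Of 22 antigen genes 3 fell (4 adjusted over the list alone; median -0.31; adjusted p = 0.382 with an estimated correlation). Of 30 chaperone genes 5 rose (median 0.19) and of 16 endothelial genes 1 fell (median -0.37), both at adjusted p = 0.42 with an estimated correlation.

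limma called 517 probe sets in P60 TR, 181 higher and 336 lower, with 1883 at an unadjusted p under 0.05. Without P60_WT_2 the count was 334. Without P60_TR_2 it was 439, of which 284 were higher and 155 lower, which turned the majority. Of 24 called probe sets of the genes named here 18 passed without any 1 array. Without P60_TR_2, Tnnt3 (-3.53), Atp2a1 (-2.80), Ckm (-3.14), Myh4 (-2.40) and Pvalb (-1.57) missed the threshold (adjusted p from 0.0551 to 0.314), as did Atp2a1, Ckm and Myh4 without P60_WT_2 (up to 0.114), Atp2a1 and Myh4 without P60_WT_3 (up to 0.0969) and Atp2a1 without P60_WT_1 (0.0595). The antigen and endothelial lists were lost without P60_TR_2 (-0.28, adjusted p = 0.0994, and -0.22, 0.234) or P60_WT_3 (-0.08, 0.268, and -0.10, 0.235). Without the 2 arrays of scan day 7, 1 of each group, 435 were called, and between those 2 arrays 329 had the same sign and 96 the opposite one. A fixed block of scan day left 383 probe sets past the threshold (279 higher, 104 lower), 144 of the 517 and 12 of the 24 of named genes among them. With the block 7 of 10 lists kept their call, at medians equal to those within that day, among them cholesterol (-1.23), muscle (-1.55), cell cycle (0.60) and regulators (0.41). Those for myelin (-0.28, adjusted p = 0.064), mast cells (-0.25, adjusted p = 0.147) and chaperones (0.24, adjusted p = 0.105) did not pass.

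**Figure D4:**
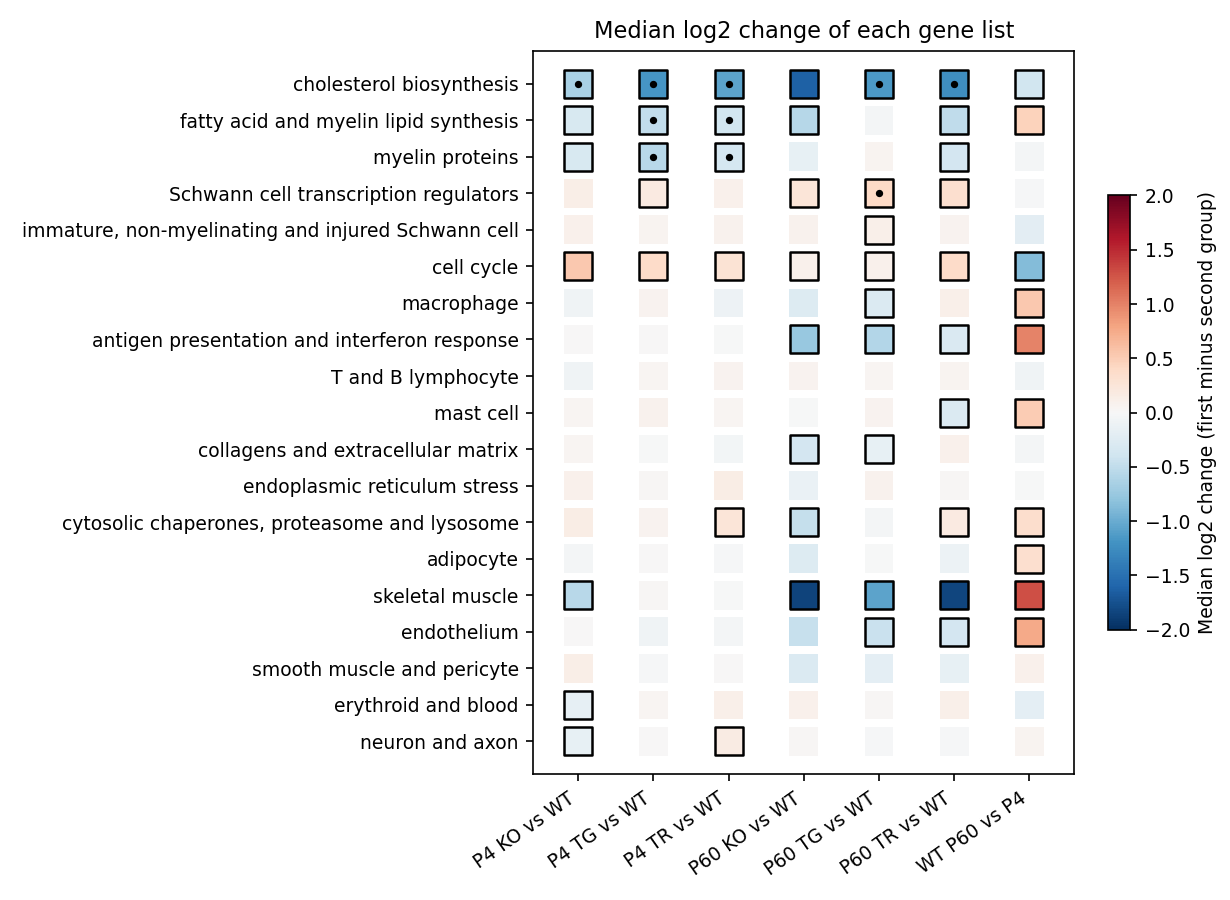
Median log2 change of the 19 gene lists (colour scale) in each comparison of a mutant with WT and of WT at P60 with P4; an outline marks a camera call at an adjusted p under 0.05, and a dot a call that also held with an estimated correlation. The cholesterol list lay between -1.64 and -0.65 in the mutants.

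Across mutants at P4, the lipid and sterol synthesis genes Scd1, Elovl6 and Mvk were lower in all 3 mutants. With Mme, Mea1 and a probe set without a single symbol these made 6 probe sets lower and 0 higher by limma in all 3. At P60, 26 probe sets were higher in all 3, among them Pou3f1, Id2, Id4, Sox2, Sox4, Fos, Csrp2, Tyrp1 and Abca1. The 87 lower in all 3 included the sterol genes Idi1, Sqle, Cyp51, Fdft1, Hsd17b7, Mvk, Mvd, Msmo1 and Sc5d, the mast cell genes Mcpt4, Hdc and Cma2, the muscle genes Pygm, Pgam2 and Ckmt2, and the growth factor genes Fgf1, Fgf4 and Igf2. The skeletal muscle list, a marker of tissue around the nerve, had a mean log2 value of 9.03 to 9.51 on P60 WT arrays and 7.07 to 8.75 on P60 mutant arrays. These shared genes were chosen after their values were seen, by limma calls without a requirement on overlap of arrays. At P4, 7 (KO and TG), 6 (KO and TR) and 23 (TG and TR) probe sets were called lower in both, against 0.118, 0.0864 and 0.18 expected if calls were independent. At P60, KO and TG shared 39 higher and 135 lower probe sets (4.73 and 29.4 expected), KO and TR 63 and 216 (5.48 and 37.7), and TG and TR 54 and 130 (2.57 and 8.01). Changes from one WT group share its noise: across probe sets, simulated changes without any mutant effect had r of 0.499 (KO and TG), 0.5 and 0.502 (TG and TR) at P4, against 0.389, 0.465 and 0.424 observed, while the covariances were 0.0303, 0.0304 and 0.0306 simulated and 0.0383, 0.0446 and 0.0343 observed. At P60 the observed r was 0.46, 0.523 and 0.584 against 0.397, 0.401 and 0.4 simulated, with covariances of 0.127, 0.158 and 0.133 against 0.0302, 0.0305 and 0.0304. Simulated sets without mutant effects shared 0 calls in limma, but with nothing to call that outcome was near certain. It does not show how much shared WT noise adds to the overlap. With 3 WT arrays per age the controls could not be split, so part of the overlap may come from the WT arrays themselves.

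In WT at P60 against P4 (n = 3 and 3), Aldh1a1, a retinaldehyde dehydrogenase gene, rose by at least 5.08 ± 0.22, to 1874 ± 396, with all P4 arrays at the floor. Dpep1, a dipeptidase gene, rose by 4.62 ± 0.31, from 68.5 to 1669 ± 211, and the cytochrome gene Cyp2e1 rose by 4.44 ± 0.38. The muscle genes Pvalb (4.74 ± 0.62) and Myh4 (4.41 ± 0.86) and the urinary protein gene Mup5 (4.64 ± 1), a member of a family of close copies, rose. Mki67 fell by 3.97 ± 0.30, from 1089 ± 214 to 67.9 ± 15.9, and the mitosis genes Cdk1 (-3.47), Aurkb (-3.47) and Ccnb2 (-2.80) and the chromatin gene Hmgb2 (-3.04) fell, with 2 P60 arrays at the floor for Cdk1 and Aurkb and 3 for Hmgb2. Pou3f1 changed by -3.35 ± 0.38 (a bound, 2 P60 arrays at the floor) and Csrp2 by -3.48 ± 0.30. H2-K1 rose by 2.24 ± 0.21, from 683 ± 36.2 to 3250 ± 401, and the immunoproteasome gene Psmb8 (3.27) and Ifit3 (at least 3.05) rose with it. The endothelial genes Cldn5 (2.69), Vwf (1.52) and Emcn (0.75), the adipocyte genes Adipoq (3.75), Lipe (2.10) and Fabp4 (1.72), and Hspa1a (2.54), Hspa1b (1.70) and the autophagy receptor gene Sqstm1 (1.16) rose. Pmp22 changed by -0.06 ± 0.11 (adjusted p = 0.77).

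With age in WT, 1 of 44 cell cycle genes rose and 26 fell (1 and 29 adjusted over the list alone; median -0.87; camera adjusted p = 4.46e-21). Of 22 antigen genes 18 rose (median 0.99; camera adjusted p = 7.24e-14) and of 9 mast cell genes 4 rose (median 0.51). For these 3 lists the adjusted p = 0.0731 with an estimated correlation. Of 16 endothelial genes 8 rose (12 adjusted over the list alone; median 0.76; adjusted p = 0.325 with an estimated correlation). Of 18 adipocyte genes 6 rose (8 risen and 1 fallen when adjusted over the list alone; median 0.34; adjusted p = 0.174 with an estimated correlation). Of 23 muscle genes 8 rose (10 and 1 adjusted over the list alone; median 1.29; adjusted p = 0.429 with an estimated correlation). Of 16 cholesterol genes 1 rose and 4 fell (median -0.38), and of 16 fatty acid genes 6 rose and 1 fell (7 and 1 adjusted over the list alone; median 0.46). Of 24 macrophage genes 4 rose (6 adjusted over the list alone; median 0.54) and of 30 chaperone genes 8 rose (9 adjusted over the list alone; median 0.35). For these 4 lists the adjusted p = 0.38 with an estimated correlation.

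limma called 1638 probe sets for age in WT, 1155 higher and 483 lower, with 3025 at an unadjusted p under 0.05. Quantile scaling gave 946 higher and 717 lower and median scaling 984 and 648, and without P4_WT_2 the count was 1076. Emcn missed the threshold without P4_WT_1 (0.62, adjusted p = 0.0744) or P60_WT_2 (0.67, adjusted p = 0.0679), and no list call was lost without any 1 array. Without the 3 arrays of scan day 6, 2 of P60 and 1 of P4, 856 were called, and on that day 806 had the same sign and 34 the opposite one. A fixed block of scan day left 582, 495 of the 1638 and 20 of the 25 genes named here among them. Cell cycle (-0.85), antigen (0.83) and muscle (2.04) were called with the block, as 9 of 10 lists were, and chaperones (0.19, adjusted p = 0.0686) were not.

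Some lists were called in none of the 6 mutant comparisons with WT nor with age. No gene of 14 on the T and B lymphocyte list passed in any of them, and the list median was -0.09 in P4 KO (adjusted p = 0.0557) and 0.06 in P60 KO (adjusted p = 0.229). The endoplasmic reticulum stress list of 24 genes had a median of 0.10 in P4 KO with 1 gene fallen (adjusted p = 0.377) and of 0.09 in P60 TG (adjusted p = 0.0939). The 12 smooth muscle and pericyte genes had a median of -0.29 in P60 KO with 4 fallen (adjusted p = 0.115). Median, mean and test differed in sign only for lists that missed the threshold: matrix, endothelium and smooth muscle in P4 KO, lymphocyte in P4 TG, skeletal and smooth muscle in P4 TR, endoplasmic reticulum stress and neuron in P60 KO, mast cell, adipocyte, erythroid and neuron in P60 TG, matrix in P60 TR, and matrix, endoplasmic reticulum stress and neuron with age in WT.

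Between mutants at P4 (n = 3 and 3 in each pair), Ugt8a was higher in KO than in TG by 1.56 ± 0.30 and Ednrb lower by 1.84 ± 0.31. The imprinted RNA gene Meg3 (2.13) and the chaperonin gene Cct3 (1.80) were higher in KO, and Snhg6 changed by -3.62 ± 0.35 and AI506816 by -3.19. Hspa1a and Hspa1b were lower than in TR by 4.31 ± 0.24 and 3.36 ± 0.23 in KO and by 4.28 ± 0.24 and 3.45 ± 0.23 in TG. Against TR, KO was higher in Hnrnpc (1.58), the splicing factor gene Smndc1 (1.44) and the zinc finger gene Zfp97 (1.27) and lower in the protease gene Ctsc (-3.28), and TG was higher in Pkp2 (1.24) and the ubiquitin-conjugating enzyme gene Ube2t (0.88) and lower in Clvs1 (-3.04 ± 0.31). limma called 46 probe sets for KO against TG (29 higher, 17 lower), 45 for KO against TR (17 and 28) and 16 for TG against TR (3 and 13; 11 and 23 with quantile scaling).

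Array omissions moved these counts widely. KO against TG was 19 to 24 without P4_KO_1, P4_KO_2 or any TG array and 78 without P4_KO_3. KO against TR was 20 without P4_KO_2, 21 without P4_TR_1, 23 without P4_KO_1, 27 without P4_TR_2 and 164 without P4_TR_3. TG against TR was 10 without P4_TG_1 or P4_TG_2 and 81 without P4_TR_3. Without the 4 arrays of scan day 4, 2 of each group, 0 probe sets were called for KO against TG. With scan day as a fixed block 77, 6 and 3 passed in the 3 pairs, 29, 3 and 0 of the called ones among them. Snhg6 and AI506816 in KO against TG, and Hspa1a, Hspa1b and, for TG, Clvs1 against TR, passed without any 1 array. In KO against TG, cholesterol (median 0.40, 2 risen), fatty acid (0.29, 2 risen), myelin (0.21, 1 risen), macrophage (-0.11), muscle (-0.69), erythroid (-0.25) and neuron (-0.14) lists were called. With an estimated correlation their adjusted p = 0.526 (cholesterol, myelin, erythroid and neuron) or 0.711. In KO against TR, cholesterol (0.37), cell cycle (0.25), lymphocyte (-0.20), chaperone (-0.10, 4 fallen), muscle (-0.39), erythroid (-0.25, 1 fallen) and neuron (-0.39) lists were called, with adjusted p from 0.0771 to 0.746 with an estimated correlation. In TG against TR only chaperones were (-0.14, 4 fallen; adjusted p = 0.964 with an estimated correlation).

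Between mutants at P60 (n = 2 and 2 in each pair), Socs3 was higher in KO than in TG by 3.26 ± 0.27, Lox by 2.71 ± 0.44 and the immune gene Fgl2 by 2.38. The Mir686 probe set (-3.80), the pore-forming protein gene Gsdme (-3.36) and the tau gene Mapt (-3.21 ± 0.44) were lower in KO than in TG, and Pmp22 was lower by 0.61 ± 0.13 (adjusted p = 0.0116). Against TR, KO was higher in the interferon-induced gene Gbp2b (3.06 ± 0.47, a bound with both TR arrays at the floor) and Sncg (2.48) and lower in Ctsc (-4.00), the Mir686 probe set (-3.76) and Snhg6 (-3.31). Xist, expressed from the inactive X chromosome of females, was higher in KO than in TR by 4.30 ± 0.82, with both TR arrays at the floor; the sex of the pooled mice is not given in the sources used here. TG was higher than TR in Fbp1 (at least 4.66 ± 0.24, both TR arrays at the floor), the small GTPase gene Rasd1 (2.75) and the membrane protein gene Tmem50b (2.32) and lower in the hemoglobin genes Hbb-b2 (-2.83) and Hba-a1 (-2.73), which have close copies, and the monocyte receptor gene Ccr2 (-2.22).

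limma called 734 probe sets for KO against TG (192 higher, 542 lower), 740 for KO against TR (148 and 592) and 144 for TG against TR (72 and 72). Quantile and median scaling gave 334 and 509, and 316 and 478, for KO against TG, and 260 and 459, and 300 and 428, for KO against TR. Median scaling gave 107 and 69 for TG against TR. Without P60_KO_2 the KO counts were 87 against TG and 93 against TR, and without P60_KO_1 1668 and 1530. KO against TG gave 227 and 226 without P60_TG_1 or P60_TG_2, KO against TR 109 and 1142 without P60_TR_1 or P60_TR_2, and TG against TR 31 without P60_TG_2. With scan day as a fixed block 6 probe sets passed for KO against TR, and with it as a random block 120 passed for KO against TG and 32 for TG against TR. None of the 6 genes named for KO against TR passed the fixed block. With the random block the 6 with the largest changes passed for KO against TG. Tmem50b (adjusted p = 0.231), Hba-a1 (0.097) and Ccr2 (0.207) missed the threshold with it for TG against TR. Socs3, Lox, Mir686, Gsdme and Mapt for KO against TG, Gbp2b, Mir686 and Snhg6 for KO against TR, and Fbp1 and Rasd1 for TG against TR passed without any 1 array. In KO against TG the cholesterol (-0.43, 4 fallen), antigen (-0.44, 2 fallen), chaperone (-0.52, 2 risen and 6 fallen) and adipocyte (-0.27, 2 fallen) lists were called, with adjusted p = 0.69 with an estimated correlation. In KO against TR the antigen (-0.57, 5 fallen), matrix (-0.45, 3 risen and 11 fallen) and chaperone (-0.64, 11 fallen) lists were called, with adjusted p = 0.765 with an estimated correlation. In TG against TR the fatty acid (0.45), myelin (0.53), cell cycle (-0.21), macrophage (-0.54), mast cell (0.24), matrix (-0.33), chaperone (-0.26), adipocyte (0.25) and muscle (0.65) lists were called. With an estimated correlation their adjusted p ran from 0.0651 to 0.474.

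The change of Pou3f1 from WT differed between P60 and P4 in every mutant, by 3.05 ± 0.57 in KO, 3.84 ± 0.57 in TG and 3.71 ± 0.57 in TR. Serpind1 differed by -2.93 ± 0.36 in TG and -3.04 ± 0.36 in TR, and Lox by -3.15 ± 0.54 and -3.01 ± 0.54. In KO the kinase anchor gene Akap9 (3.24), the helicase gene Ddx6 (2.68), Pvalb (-3.36), Serpinf1 (-3.34), a secreted serpin gene, and the actin-severing gene Gsn (-3.27) had the other largest differences. In TG these were Fbp1 (4.33), Tyrp1 (3.81, the change at P60 itself because all P4 WT and TG arrays lay at the floor) and the surface antigen gene Cd99 (-2.83), and in TR Csrp2 (2.99), Tyrp1 (2.82) and Fgf4 (-2.90). limma called 845 probe sets for KO (134 higher, 711 lower; 223 and 415 with quantile scaling, 256 and 471 with median scaling), 144 for TG (69 and 75) and 62 for TR (24 and 38). For TG the majority turned with quantile (94 and 78) and median scaling (81 and 68). The KO count was 36 without P60_KO_2, 133 without P4_KO_2, 208 without P60_WT_3, 255 without P4_KO_1, 260 without P4_WT_2, 557 without P4_WT_3 and 1861 without P60_KO_1; the TG count was 50 without P60_TG_2, 81 without P4_WT_3, 84 without P4_WT_1 and 91 without P60_WT_2. With scan day as a fixed block 12 probe sets passed for KO and 14 for TR, 6 and 3 of the called ones among them, and with it as a random block 81 passed for TG. Of the 6 genes named in each mutant, none passed the fixed block in KO or TR, with Pou3f1 at adjusted p = 0.19 and 0.181. All 6 passed the random block in TG. Of the 6 genes named in each mutant, Pou3f1 passed without any 1 array in KO, Fbp1, Pou3f1, Tyrp1 and Serpind1 in TG, and Pou3f1, Csrp2, Serpind1 and Fgf4 in TR.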

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

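The tests of single array P60_KO_2 and of the cholesterol list were chosen after those results were seen; the other splits of the arrays, the tests of scan day and genotype in P60 KO and the test of genes near Pmp22 were fixed before.

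The change from WT differed between P60 and P4, by a test of the difference itself in limma, for 845 probe sets in KO, 144 in TG and 62 in TR. Among the genes named in the report this held for 26 probe sets in KO, 18 in TG and 14 in TR, given here as the change at P60 minus the change at P4 on the log2 scale. In KO the difference was positive for Akap9 (3.24), Pou3f1 (3.05), Ddx6 (2.68), Socs3 (2.20), Rfc1 (2.16), Abca1 (1.87), Mki67 (1.82) and Id2 (1.26). It was negative for Tap2 (-0.65), Adk (-0.70), H2-K1 (-1.14), Fads1 (-1.27), Rnf227 (-1.29), Pygm (-1.41), Sqle (-1.50), Hnrnpc (-1.58), Pvalb (-1.71 and, by a second probe set, -3.36), Rnf166 (-1.79), Idi1 (-1.89), Sc5d (-2.08), Ifit3 (-2.31), Fdps (-2.80), Tnni2 (-3.14), Gsn (-3.27) and Serpinf1 (-3.34). For Tap2, Pygm and Ifit3 all P4 WT and KO arrays lay at the floor, so no P4 change could be measured and the difference is the P60 change alone. For Rnf227 all P60 WT and KO arrays did, so its difference is the P4 change with the sign turned. Without P60_KO_2, 8 of the 26 probe sets passed: those of Pou3f1, Socs3, Id2, Tap2, Pygm, Idi1 and Ifit3 and the second of Pvalb, and the KO count was 36.

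In TG the difference was positive for Fbp1 (4.33), Pou3f1 (3.84), Tyrp1 (3.81), Csrp2 (3.62), Sowaha (3.08), Rit2 (2.21), Id2 (2.12), Ugt8a (2.04), Scd1 (1.68) and Ndrg1 (0.79). It was negative for Pygm (-1.41), Fgf4 (-2.26), A2m (-2.31), Slc22a2 (-2.54), Cd99 (-2.83), Serpind1 (-2.93) and Lox (-3.15 and, by a second probe set, -2.71). In TR it was positive for Pou3f1 (3.71), Csrp2 (2.99), Tyrp1 (2.82), Mki67 (2.74), Adam2 (2.60), Id2 (2.23) and Scd1 (1.27) and negative for Pygm (-1.41), Stmn1 (-1.93), Hspa1b (-1.94), Hspa1a (-2.41), Fgf4 (-2.90), Lox (-3.01) and Serpind1 (-3.04). All P4 arrays compared lay at the floor for Tyrp1, Pygm and Slc22a2 in TG and for Pygm in TR, so these differences too are the P60 changes alone.

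Among gene lists, camera called a difference in KO for cholesterol biosynthesis (median -0.71), antigen presentation (-0.76), chaperones (-0.67), Schwann cell regulators (0.17) and erythroid genes (0.30), each at adjusted p = 0.47 with an estimated correlation, and for skeletal muscle (-1.41; adjusted p = 0.632 with an estimated correlation). In TG it called fatty acid synthesis (0.22), macrophage (-0.42), antigen presentation (-0.54) and skeletal muscle (-0.88), each at adjusted p = 0.479 with an estimated correlation, Schwann cell regulators (0.30; adjusted p = 0.28) and myelin proteins (0.55; adjusted p = 0.101). In TR it called Schwann cell regulators (0.24; adjusted p = 0.141 with an estimated correlation), antigen presentation (-0.25; adjusted p = 0.691), skeletal muscle (-1.87; adjusted p = 0.189) and mast cells (-0.44), the last also with an estimated correlation (adjusted p = 0.0393).

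P60 KO against WT called 1568 probe sets, against 418 and 517 in TG and TR, and 1 array that stood apart may account for most of this excess, since 183 passed without P60_KO_2 and 2325 without P60_KO_1, with 152 called in the same direction both ways. Over the 2325, whose choice by P60_KO_2 enlarges its own change, P60_KO_1 moved the same way against WT for 91.7%, with a median change of 0.475 against 1.21, and the TG and TR arrays, which share that WT, for 58.2% to 79.3%. Against the other P60 mutants, P60_KO_1 differed by 0.239 of what P60_KO_2 did (95% interval over probe sets 0.221 to 0.255, without the spread between pools), so that an effect of the genotype in both arrays stays open. The scan day of both KO arrays also stays open: the P4 TG array of that day deviated the way the calls went for 40.2% of them, but this is 1 array, and the other P4 arrays ranged from 26.7% to 66.3%. Genotype, the mix of mice in the pool and the handling of P60_KO_2 cannot be told apart with 2 arrays. Xist was 2228 on P60_KO_2 and 523.6 on P60_KO_1, so the mix of sexes in the pools stays open too.

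The cholesterol list was lower in every mutant group at both ages. Chance in the WT arrays that the mutants share was not decided. Exact two-sided permutation tests used the list mean per array. Mutants differed by -1 at P4 (9 against 3 arrays, permutation p = 0.00455) and -1.39 at P60 (6 against 3, permutation p = 0.0119). Each p was the smallest possible. The list was chosen for these tests after it was seen to be lower in every mutant group. The tests also pooled the mutants and left out scan day. Fewer myelinating Schwann cells as the whole cause is argued against because the list fell beyond the myelin protein list, by -0.642 at P4 (p = 0.00455) and -1.17 at P60 (p = 0.0119), again the smallest exact permutation p possible. These p-values are likewise not adjusted for the choice of the list. Scan day as the whole cause was not decided. With it as a block the list was called lower, at the preset correlation between genes, in 5 of 5 comparisons that could be fitted. These calls are not independent. P4 TR and P60 TR rested on 1 array of each group, on days 3 and 7, with medians of -1.18 and -1.23. P4 KO, P4 TG and P60 KO were linked to WT through the same day 7 arrays. P60 TG could not be fitted, and P60 KO had camera adjusted p = 0.0641 with an estimated correlation and no block. An effect of altered Pmp22 on sterol synthesis in Schwann cells may remain as a hypothesis, untested. It stands next to chance in the WT arrays, scan day, pooling and dissection, which the design does not separate. Sterol synthesis measured in Schwann cells isolated from single mice could decide it.

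Genes that changed in KO might lie near Pmp22, in donor-strain DNA carried along with the null allele. Among 165 tested neighbours, up to 200 genes to each side, 0 of the 26 genes called in P4 KO were found (Fisher exact p = 1; odds ratio 0, interval 0 to 6.88). In P60 KO without P60_KO_2, 4 of 148 were, against 3.23 expected (odds ratio 1.25, interval 0.332 to 3.34, Fisher exact p = 0.566). With all arrays of P60 KO, 27 of 1267 were, against 27.6 expected (odds ratio 0.972, interval 0.615 to 1.48, Fisher exact p = 1), and in TG and TR, which do not carry the null allele, odds ratios ran from 0 to 0.838. The intervals leave both absence and enrichment open, and no strain information was tested.

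The arrays of each comparison of 3 against 3 can be split in 10 ways, too few for a share under 0.05. In limma, the real split called 39 probe sets for P4 KO against WT (highest other 2), 61 for TG (highest other 4), 1638 for age in WT (highest other 2), 45 for KO against TR (highest other 6) and 46 for KO against TG (highest other 0), each the only 1 of 10 with as many. For P4 TR against WT the real split called 48 and another, with P4_TR_1, P4_TR_2 and P4_WT_2 on one side, 53, so 2 of 10 gave as many. That split puts both arrays of scan day 3 together, with 16 passing when scan day was a block. It also joins the 3 arrays with the highest skeletal muscle list means (8.35 to 9.07, against 7.62 to 7.83). The same 3 arrays had the highest Xist (1003 to 1192, against 519.8 and 502.9 on P4_WT_1 and P4_WT_3), with P4_TR_3 near at 941.9. For P4 TG against TR the real split called 16 and the highest other, with P4_TR_3 beside P4_TG_1 and P4_TG_2, called 20, so 2 of 10 gave as many.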

How the results depend on the processing

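Chosen after the data were seen were the random block of scan day where a fixed block could be fitted and the fit without P60_KO_2 for comparisons without P60 KO. Chip lot was planned but is empty in the files, so it was not run. A change or list call counted as kept if it held direction and side of the threshold. For counts of probe sets, shared calls, lists or named genes, kept means within a fixed ratio of the main count, whatever the split. Of 318 results, 310 were kept without a trend or with median scaling, 298 with the floor at the 10th percentile and 302 with quantile scaling. The number was 303 with log2 of the value plus 50, 306 with replicate number as a block, 288 without a filter and 279 with the random block. Whether replicate numbers pair arrays stays open, since the labels do not say what a number shares. Of pairs with the same number, 26 of 66 correlated above 0.1 (40 of 126 with different numbers), and 18 of 30 at the same age. Among these were all 3 for P4 WT and TR and all 3 for P4 KO and TG, but not all for the 4 other P4 pairings. Groups of 2 arrays deviate from their mean in mirror image, so each r between 2 P60 mutants enters these counts more than once. In all, 14 of 21 arrays best matched their own number. Of 255 results, 104 were kept with the fixed block, which has 5 residual degrees of freedom and in simulated data found 15.2% of 4-fold changes. Of the 255, 3 reversed. Fits on the compared groups alone kept 160 of 318, and they have fewer arrays for the error. Fewer arrays alone do not account for P60 KO, which went from 1568 to 5 probe sets. With the same numbers of arrays, P60 TG went from 418 to 113 and P60 TR from 517 to 79. The main fit takes a common error for all groups, so its 1568 calls assume that the P60 KO arrays spread like the others. No list call reversed with either scaling. Low signal limits genes near the floor, where falls are bounds and errors and adjusted p can be too small. Causes below were not tested.

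With own groups only, probe sets changed were 10, 0 and 6 in P4 KO, TG and TR, 5, 113 and 79 in P60 KO, TG and TR, 7, 6 and 2 in P4 KO against TG, KO against TR and TG against TR, and 488 for the KO effect by age. They were 0 in limma for all P60 pairs, with 1559, 1022 and 1005 at an unadjusted p under 0.05, and 846 for P4 TG. The calls shared between mutants were 0 at P4 and 33 at P60, and 72 probe sets of named genes passed. With scan day as a fixed block, counts were 6, 5 and 16 in P4 KO, TG and TR, 5 in P60 KO, 582 for age in WT, 77, 6 and 3 in the P4 pairs, 6 in P60 KO against TR, and 12 and 14 for the KO and TR effects by age, with 4 calls shared at P4. That block reversed Mb (-0.30) and Actn3 (0.74) in P4 KO and Id2 (-0.013) in P4 TG, none called before or after. With the random block, counts were 17 in P4 KO, 875 in P60 KO, 174 in P60 TG, 182 in P4 KO against TG, 120, 299 and 32 in P60 KO against TG, KO against TR and TG against TR, and 403, 81 and 98 for the KO, TG and TR effects by age.

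With the filter at the 40th percentile, fewer probe sets were tested and 23 changed in P4 KO, 29 in P4 KO against TG, 6 in P4 TG against TR, 79 in P60 TG against TR and 31 for the TR effect by age. No filter gave 22 for P4 KO against TG. P4 TG against TR gave 34 with quantile scaling and 30 with the replicate block. The TR effect by age gave 96 with the floor at the 40th percentile and 98 without P60_KO_2 in the fit. With an estimated correlation 10 of 55 list calls held, and cholesterol in P60 KO (-1.64) had adjusted p = 0.0641.

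Pmp22 in P4 KO passed with quantile scaling (-0.53, adjusted p = 0.0144), median scaling (-0.55, 0.0435), log2 of the value plus 50 (-0.49, 0.0345), the 40th percentile filter (-0.49, 0.0319) and without P60_KO_2 in the fit (-0.49, 0.0388). In P60 KO it did not pass with median scaling (-0.27, adjusted p = 0.157), own groups (-0.40, 0.203), the fixed block (-0.37, 0.652) or the random block (-0.40, 0.0898).

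Without 1 array, counts ranged from 13 to 46 in P4 KO, 25 to 74 in P4 TG, 16 to 80 in P4 TR, 183 to 2325 in P60 KO, 121 to 394 in P60 TG, 334 to 476 in P60 TR and 1076 to 1370 for age in WT. In pairs they ranged from 19 to 78, 20 to 164 and 10 to 81 at P4 and from 87 to 1668, 93 to 1530 and 31 to 162 at P60 (KO against TG, KO against TR, TG against TR). For effects by age they ranged from 36 to 1861 (KO), 50 to 181 (TG) and 42 to 87 (TR). Pmp22 ranged from -0.53 to -0.44 in P4 KO, -0.14 to -0.06 in P4 TG, -0.19 to -0.02 in P4 TR, -0.52 to -0.28 in P60 KO, 0.10 to 0.31 in P60 TG, -0.33 to -0.28 in P60 TR and -0.10 to -0.02 for age. The cholesterol list ranged from -0.74 to -0.51, -1.36 to -1.06 and -1.25 to -1.04 in P4 KO, TG and TR and from -1.72 to -1.50, -1.24 to -1.01 and -1.35 to -1.25 at P60. Mb in P4 KO ranged from -0.0198 (without P4_WT_1) to 1.87.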

Other observations

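The skeletal muscle list, fixed as a marker of tissue around the nerve, differed between arrays of 1 group as well as between groups. Its mean log2 value per array ran from 9.03 to 9.51 in P60 WT, from 7.07 to 7.84 in P60 KO, from 8.07 to 8.75 in P60 TG and from 7.37 to 7.94 in P60 TR. In P4 WT it ran from 7.62 to 9.07. The cholesterol list had group means (± SD over arrays) of 9.61 ± 0.127 in P4 WT, 8.86 ± 0.164 in P4 KO, 8.38 ± 0.368 in P4 TG and 9.32 ± 0.114 in P60 WT, against 7.66 ± 0.169 in P60 KO, 8.21 ± 0.0766 in P60 TG and 7.91 ± 0.132 in P60 TR.

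Xist, looked at on single arrays after its values were seen, ran from 941.9 to 1192 on the P4 TR arrays and was 1003 on P4_WT_2, against 237.5 to 737.7 on the other P4 arrays. Eif2s3y, from the Y chromosome, was between -1.89 and 27.7 on those 4 arrays and between 81.3 and 150.8 on the other P4 arrays. At P60 Xist ran from 226.6 to 629.6 in WT and was 523.6 and 2228 in KO, 144.5 and 1476 in TG, and 7.61 and 3.47 in TR, below the floor. Eif2s3y lay above the floor on each P60 array, those with the highest and lowest Xist included, at 67.7 to 169.8 in WT, 124.8 and 107.3 in KO, 258 and 91.7 in TG, and 254.5 and 85.4 in TR. The sex of the mice in each pool is not given, and no comparison was adjusted for it. By Xist, TR lay above P4_WT_1 and P4_WT_3 at P4 and below all WT arrays at P60. For TR, a difference in sex between pools therefore cannot be told apart from genotype at either age, nor in the effect by age. At P60, Xist on P60_KO_2 and P60_TG_2 lay above all WT arrays and above their partner arrays, while Eif2s3y lay within the WT range. Omitting these arrays lowered the counts of their comparisons with WT most, so the sex of the pools stays open for KO and TG as well.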
